A study of Homo sapiens with 6 samples.

How the data were processed

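Gene expression was measured in 6 Affymetrix microarrays of total RNA from subclones of DLD-1, an established human colorectal adenocarcinoma line. The cells had been grown for 96 h in 3D type I collagen at 1 mg/ml, without treatment. The arrays formed 2 groups of 3, labelled α-Cat and Δα-Cat, and each group came with replicate numbers 1 to 3. The labels do not spell out either name; α-Cat was read as α-catenin, and the CTNNA1 values in each array served as the check of that reading.

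The deposited values were made by the authors with Affymetrix Expression Console and RMA (background correction, quantile normalization and a summary over the probes of a transcript cluster), per the submitters' processing notes; versions, settings and annotation release were not given in the sources used here. The scale was not stated. It was taken to be log2 because RMA gives log2 values and because the rows kept lay between 1.26 and 14.24 with nearly equal quartiles on all arrays. A transcript cluster is the array's unit of a gene, summarised from its probes. Of 70513 rows, 4987 held at least 1 value without a decimal point, with values up to 999, and 4986 of these had no decimal point in any value. They could not be log2 values and were left out. Among them were 505 transcript clusters of assembled chromosomes, and 1091 rows were in the gene annotation with no more than 1 symbol, so some genes may not be analysed here. The other 65526 transcript clusters were tested. A second table was not used: the names of its 6 columns of per-sample values match no sample label, and its decimal points were damaged.

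Gene names came from the platform annotation given for the value table and the RefSeq gene table of assembly GRCh38.p14, which was used for names, gene types and the order of neighbouring genes only. Of the clusters tested, 22686 had 1 gene symbol, 1385 had several and 41455 had none; no gene was named from a cluster with several. The single-symbol clusters covered 22376 genes, 296 of them with more than 1 cluster. Each gene was represented by its single-symbol cluster with the highest mean level.

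Differences are Δα-Cat minus α-Cat throughout. They were fitted over all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no covariate), and adjusted by the Benjamini-Hochberg method over all clusters tested. A call required an adjusted p under 0.05, and a separate count also required at least a 2-fold change. All adjusted p-values of single genes are from limma. Values in groups are means ± SD, and changes carry the standard error (SE) of the fit. A total of 36 gene lists was fixed before the data were examined; 35 had at least 5 measured members and were tested with limma's camera, with a preset inter-gene correlation of 0.01. The list of mitochondrial RNAs had 0 members named by the annotation and was not analysed here. Camera with an estimated correlation and limma's fry were run beside it. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the tables, and matplotlib 3.10.9 for the plots.

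The genes named in the text followed a rule set before the data were examined. It took 10 genes of the cadherin-catenin complex and its partners whatever their values. It also took the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap, leaving out uncharacterised loci, small RNAs, microRNA host genes, olfactory receptors and open reading frame names. From each list it took up to 4 called members with the largest change or, where none was called, up to 2 members with the smallest p. Exceptions are stated where they occur. CTNND1, which the rule names, has no single-symbol cluster and is not reported.

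Residuals were compared between arrays of the 2 groups. After subtracting group means, those of same-numbered arrays correlated at 0.219, 0.214 and 0.128 for numbers 1, 2 and 3, all above 0.1. Every pair of differently numbered arrays of the 2 groups correlated below 0. The residuals of a group sum to 0, so positive values for same-numbered arrays force the others to be negative on average. With few ways to match 3 arrays to 3, a best match by number can arise by chance. Pairing by number is therefore possible but not established. The labels do not say what a number stands for. The planned fit ignored the number, and the fit with the replicate block was run as an alternative, in which 156 clusters were called. Its adjusted p is given beside a gene only where it changes the call.

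The fit was tested on simulated data with 65526 clusters and 50 changed clusters per fold size. It recovered 48% of the changed clusters at 1.5-fold, 72% at 2-fold, 100% at 3-fold and 98% at 4-fold. The fit with the replicate block recovered 0, 26, 41 and 45 of 50 at these sizes, in simulated arrays without pairing, so changes near 1.5-fold can be missed with the block. Among the simulated calls, 9 were unchanged clusters, and 0 clusters and 0 lists were called when no change was simulated. The clusters were simulated independently of each other. The 0 lists therefore do not test calls of lists whose members vary together, such as the cell cycle list, with an estimated correlation of 0.704. With 3 arrays per group, the number of arrays limits the precision.

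Alternatives planned before the data were examined were the replicate block, trended and robust eBayes, array weights, repeated quantile normalization, cyclic loess, median centring, a filter on dim clusters, single-symbol clusters only, an unmoderated unequal-variance test per cluster, averaging of a gene's clusters, limma's treat, the other list tests and leaving out each array. The planned exchange of the gene-level table for the series matrix values was not run, because the series matrix values are the ones analysed. Rows for background controls were among those left out, so no detection call was made. As a reference for dim signal, 364 olfactory receptor genes had a median level of 2.58 and a 95th percentile of 4.43, and 66.1% of all genes lay above that percentile, which set the genes counted as expressed in the scan along chromosomes.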

Results

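The data comprised 3 arrays of α-Cat cells and 3 of Δα-Cat cells, 2 subpopulations derived from the colorectal line DLD-1 and grown for 96 h in 3D collagen. Median log2 levels per array ranged from 4.02 to 4.07. The comparison asks how gene expression differs between the subpopulations in a collagen matrix. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

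CTNNA1, which encodes αE-catenin, the link between the cadherin-catenin complex and actin, was lower in all 3 Δα-Cat arrays. Its log2 level was 6.50 ± 0.07 (SD, n = 3) in Δα-Cat and 7.73 ± 0.06 (SD, n = 3) in α-Cat, a 2.35-fold decrease (log2 change -1.24, SE 0.06, adjusted p = 0.00212). The Δα-Cat arrays read 6.55, 6.52 and 6.41, and the α-Cat arrays 7.79, 7.68 and 7.71. The labels do not say which part of the gene, if any, was altered, and a cluster summarises probes along the whole transcript. CTNNA2 and CTNNA3, the neural and heart-enriched α-catenins, lay at 3.12 and 2.37 in Δα-Cat and at 3.15 and 2.36 in α-Cat, and did not pass the test. Of the partners of α-catenin, none passed. The log2 change was 0.06 (SE 0.07) for CTNNB1 (β-catenin), 0.07 (SE 0.05) for JUP (plakoglobin), 0.26 (SE 0.08, adjusted p = 0.313) for CDH1 (E-cadherin), 0.01 (SE 0.07) for CDH3 (P-cadherin) and 0.14 (SE 0.08) for VCL (vinculin). CTNNAL1, an α-catenin-like gene, had a change of -0.50 (SE 0.12, adjusted p = 0.198).

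KRT20, a keratin of differentiated intestinal epithelium, rose most among the named genes, from 4.40 ± 0.10 to 9.15 ± 0.41 (SD, n = 3 each), a 26.8-fold increase (adjusted p = 0.000832). SLPI, a secreted inhibitor of leukocyte proteases, rose 2.96-fold, and KLK7, a secreted serine protease, rose 3.22-fold (both adjusted p = 0.000832). The kinase gene RPS6KA6 rose 3.55-fold, the heat shock protein gene HSPH1 3.27-fold and SH3BGRL 3.11-fold. S100A4, a calcium-binding protein linked to cell motility, and TIMP3, an inhibitor of metalloproteinases, each rose 2.28-fold, the transcription factor NFIB 2.24-fold and the kinase DAPK1 2.18-fold (adjusted p = 0.0374).

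SLC44A4, a choline transporter-like protein, fell most, from 8.53 ± 0.29 to 6.03 ± 0.16 (SD, n = 3 each), a 5.67-fold decrease (adjusted p = 0.00251). The neutrophil-attracting chemokine CXCL5 fell 3.69-fold. LGR5, a receptor for R-spondins and a marker of intestinal stem cells, fell 3.41-fold (adjusted p = 0.0463), and the long noncoding RNA UCA1 fell 3.31-fold (adjusted p = 0.044). KLHL4 fell 3.00-fold, and HLTF, a chromatin remodelling helicase, fell by 1.58 on the log2 scale. OLR1, a receptor for oxidised lipoprotein, fell 2.96-fold, the transcription factor NFIA 2.49-fold and POF1B, an actin-binding junction protein, 2.44-fold. No detection call was possible, so folds are those of the deposited values. The mean in α-Cat lay below 4.43, the 95th percentile of olfactory receptor genes, for KRT20, RPS6KA6, KLK7 and SH3BGRL. In Δα-Cat it did so for KLHL4, and in both groups for HLTF. Among the named list members that were called, it did so in α-Cat for NECTIN3 and in Δα-Cat for ABCB1. List members named below without a call over all clusters included dim ones: FN1, GBP1 and LUM in both groups and AKR1C1 in α-Cat. In each case the level on that side was not shown to exceed background.

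**Figure D1:**
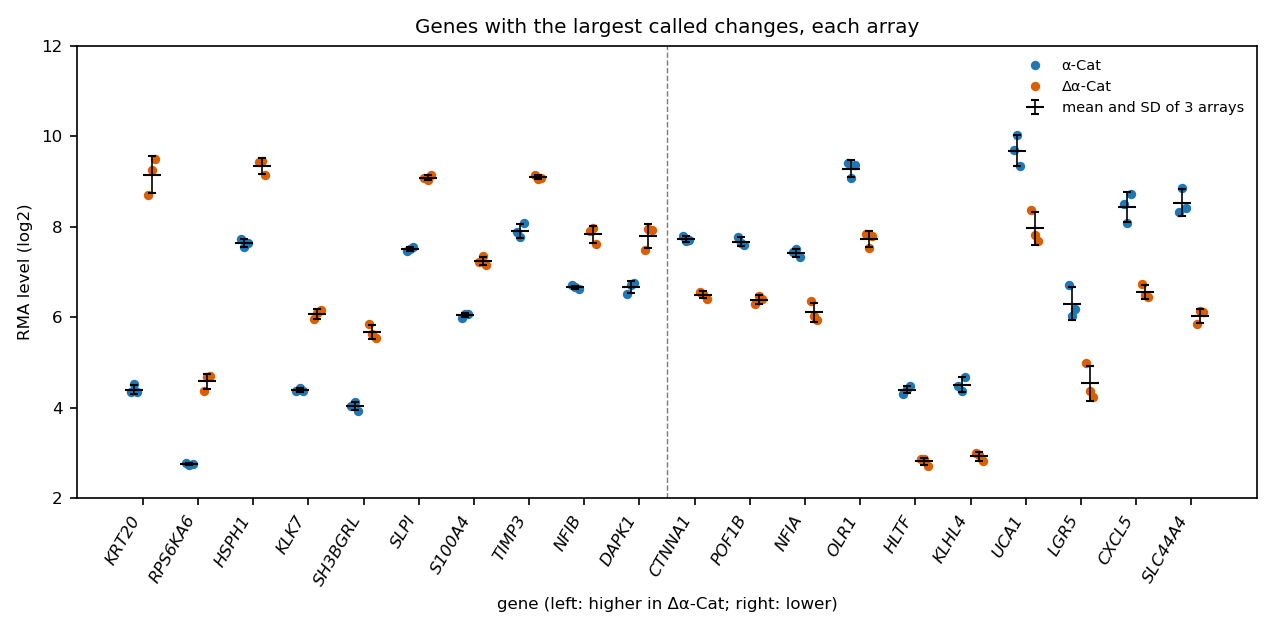
RMA log2 level (vertical axis) of the 10 genes with the largest called increase (left of the dashed line) and the 10 with the largest called decrease (right) in Δα-Cat; dots are single arrays, and black marks are the mean and SD of 3 arrays. KRT20 had means of 4.40 in α-Cat and 9.15 in Δα-Cat, and SLC44A4 of 8.53 and 6.03.

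Over all transcript clusters, limma called 224 of 65526, 138 higher and 86 lower in Δα-Cat, and 51 of these changed at least 2-fold (32 higher, 19 lower). Of the called clusters, 82 had no symbol or several (54 higher, 28 lower). Represented by 1 cluster each, 140 genes were called, 83 higher and 57 lower, of which 134 code for protein. Groups did not overlap in 15.4% of clusters, where chance gives 10%. When only single-symbol clusters were tested, 658 genes were called, 368 higher and 290 lower, and all 140 were among them. That fit also called members of lists in which the test over all clusters called none: OVOL1, EHF and KLF5 (epithelial), PTK2, LIMS1 and ACTN1 (integrin and focal adhesion), CEACAM6, GADD45A, SPDEF, MUC1 and AKR1C1 were higher. TNS4, PKP2, ICAM2, CDC25C, FN1, LTBP1, KLK12, GCLC, CD14 and TFRC were lower. EHF, ACTN1 and TNS4 are outside the naming rule and were named after their values were seen. In lists that already held a call, the same fit called 4 higher and 0 lower for ATF4 and endoplasmic reticulum stress, 4 and 1 for hypoxia and glycolysis, 3 and 2 each for colonocyte, Wnt, and TGF-β and BMP genes, 3 and 1 for adherens junctions, 2 and 2 for MAPK feedback, 2 and 1 for NF-κB, 1 and 3 for xenobiotic genes, and 1 and 1 each for tight junctions and epithelial-mesenchymal transition. Without 1 array the gene count fell to 80 (without Δα-Cat replicate 1), 36 (α-Cat replicate 2), 29 (Δα-Cat replicate 2), 29 (Δα-Cat replicate 3), 24 (α-Cat replicate 3) and 21 (α-Cat replicate 1); KRT20, CTNNA1, SLC44A4, RPS6KA6, HSPH1, KLK7, SH3BGRL, SLPI, S100A4, KLHL4, HLTF, POF1B and BIK were called in all 6 of those fits. TIMP3 was called in 5, OLR1 in 4, CXCL5, NFIB and NECTIN3 in 3, NFIA in 2, LGR5, UCA1, DAPK1 and CLDN2 in 1, and CD44, EGLN3, CYP51A1, PHGDH, MMP14, EREG, SMAD9 and ABCB1 in 0.

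Few adherens and tight junction genes were called, but the share over all genes was smaller still, at 140 of 22376. Of 25 measured adherens junction genes, 1 rose and 1 fell: NECTIN3, an adhesion molecule of adherens junctions, rose by 1.08 (SE 0.09, adjusted p = 0.00778), and CTNNA1 fell. The change was positive in 21 of the 25. Adjusted over the list alone, 4 were higher and 2 lower. The list was not called (camera adjusted p = 0.0845, fry adjusted p = 0.063). Among 26 tight junction genes, CLDN2, a pore-forming claudin, fell by 0.58 (SE 0.06, adjusted p = 0.0162, and 0.0524 with the replicate block) and 25 did not pass; adjusted over the list alone, 1 was higher and 1 lower (camera adjusted p = 0.847). Of 15 desmosome genes 0 passed over all genes and 1 was lower adjusted over the list alone (camera adjusted p = 0.803); PKP2 had a change of -0.28 (adjusted p = 0.116) and PERP of -0.24 (adjusted p = 0.481). KRT20 was the only one of 13 measured keratins to pass over all genes or adjusted over the list alone. The keratin list was called higher (camera adjusted p = 0.0224; adjusted p = 0.951 with an estimated correlation), with a median change of 0.05. That call was lost without α-Cat replicate 1 (adjusted p = 0.0814), without Δα-Cat replicate 3 (adjusted p = 0.192) and with trended, robust eBayes (adjusted p = 0.0516).

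The list of epithelial genes was called higher, with a median change of 0.12 and a positive change in 21 of 24 members (camera adjusted p = 1.1e-05; adjusted p = 0.574 with an estimated correlation). No member passed over all genes and 6 were higher adjusted over the list alone. OVOL1 and KLF5, epithelial transcription factors, had changes of 0.47 (adjusted p = 0.067) and 0.50 (adjusted p = 0.0873, and 0.0344 without Δα-Cat replicate 1). Of 20 genes of epithelial-mesenchymal transition, S100A4 rose and 19 did not pass; adjusted over the list alone, 1 was higher and 1 lower (camera adjusted p = 0.803).

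Cell cycle genes lay lower on average in Δα-Cat, with a negative change in all 39 measured members and a median of -0.27. The groups overlapped in the list mean, which was 7.695 in Δα-Cat replicate 1 and 7.682 in α-Cat replicate 2. The list was called lower (camera adjusted p = 6.74e-15; adjusted p = 0.951 with an estimated correlation, which was 0.704). No member passed over all genes, and 14 were lower adjusted over the list alone. CDC25C, a phosphatase that starts mitosis, had a change of -0.53 (SE 0.09, adjusted p = 0.0978), and CENPF, a kinetochore protein, of -0.61 (SE 0.13, adjusted p = 0.161).

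The list of ATF4 and endoplasmic reticulum stress genes was called higher, with a median change of 0.16 and a positive change in 23 of 28 members (camera adjusted p = 1.72e-07; adjusted p = 0.574 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, rose by 0.45 (SE 0.06, adjusted p = 0.0474, and 0.084 with the replicate block). The other 27 did not pass, and 11 members were higher adjusted over the list alone. The oxidative stress list was not called (camera adjusted p = 0.156): 0 of 20 passed, and adjusted over the list alone 6 were higher and 1 lower. It was called higher without α-Cat replicate 1 (adjusted p = 0.0254) and without Δα-Cat replicate 3 (adjusted p = 0.0179). AKR1C1, an aldo-keto reductase, had a change of 0.55 (adjusted p = 0.0794), and GCLC, of glutathione synthesis, of -0.30 (adjusted p = 0.117). Among 29 hypoxia and glycolysis genes, EGLN3, a prolyl hydroxylase, rose by 0.61 (SE 0.09, adjusted p = 0.0495, and 0.094 with the replicate block) and 28 did not pass; 6 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.709). CYP51A1, a sterol demethylase, rose by 0.41 (SE 0.06, adjusted p = 0.0495, and 0.099 with the replicate block) as the only called gene of 20 for cholesterol synthesis. That list had a negative median of -0.08 (camera adjusted p = 0.343, and 0.0235 without Δα-Cat replicate 2), with 1 higher and 1 lower adjusted over the list alone. EGLN3 and PHGDH also missed the threshold with cyclic loess (adjusted p = 0.063 and 0.0503) and median centring (0.0718 and 0.0548), and CYP51A1 with median centring (0.0761). None of 19 p53 targets passed, with 0 adjusted over the list alone (camera adjusted p = 0.836); TP53I3 had a change of 0.25 and CDKN1A of 0.24.

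**Figure D2:**
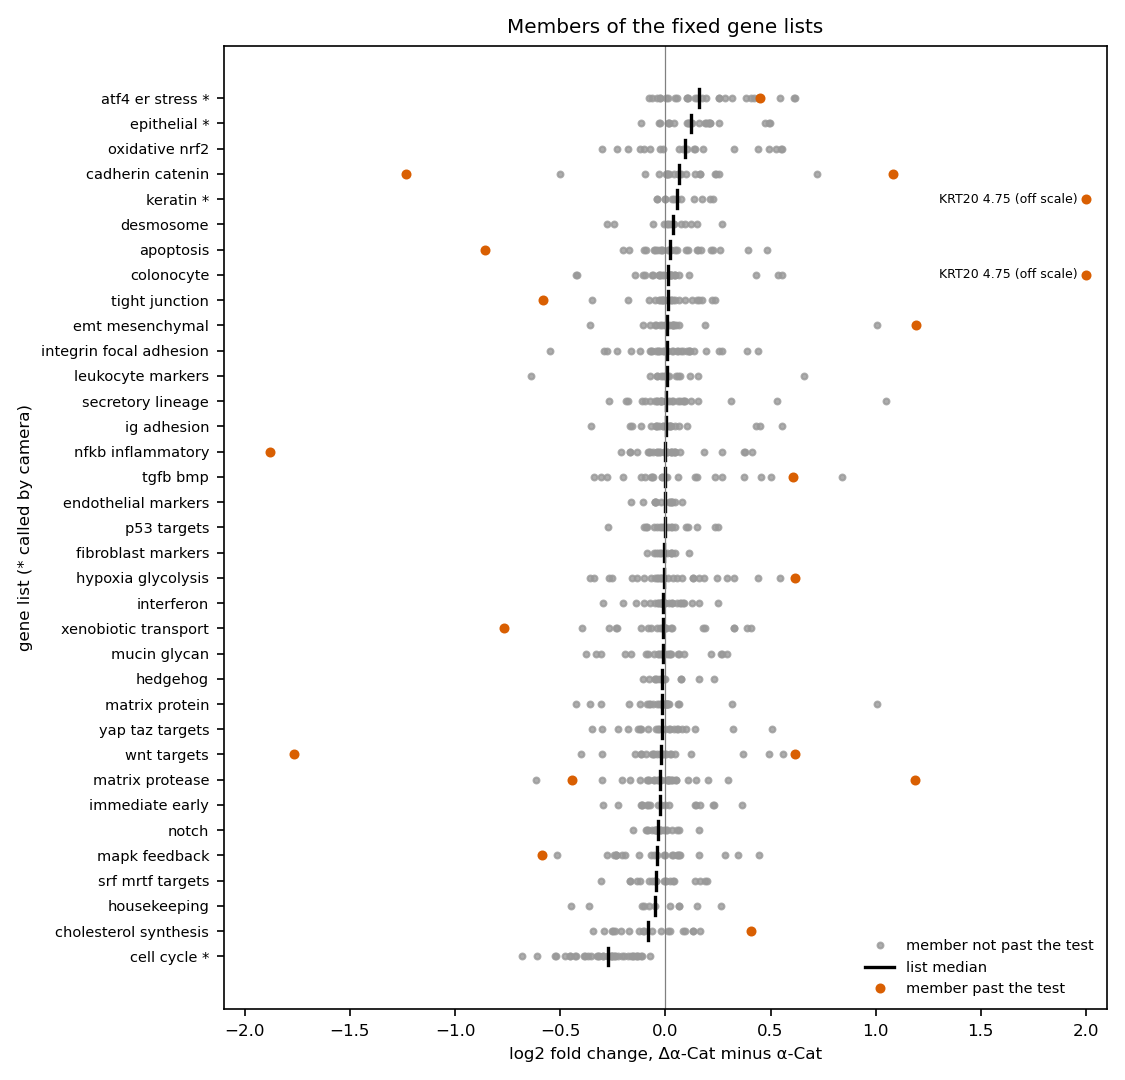
Log2 fold change of Δα-Cat minus α-Cat (horizontal axis) for each measured member of the 35 tested gene lists (vertical axis, ordered by median); orange dots passed the test over all clusters, grey dots did not, black bars are list medians and asterisks mark lists called by camera. All 39 cell cycle genes lie below 0, with a median of -0.27, and KRT20 is drawn at the edge with its value of 4.75.

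Matrix genes went both ways. Of 33 matrix proteases and inhibitors, TIMP3 rose by 1.19 (SE 0.09, adjusted p = 0.00575) and MMP14, a membrane-bound collagenase, fell by 0.45 (SE 0.05, adjusted p = 0.0345, and 0.0784 with the replicate block). The other 31 did not pass; adjusted over the list alone, 2 were higher and 3 lower (camera adjusted p = 0.803). None of 27 matrix protein genes passed and 2 were lower adjusted over the list alone (camera adjusted p = 0.343), with a change of -0.36 (adjusted p = 0.0794) for FN1 (fibronectin) and -0.43 (adjusted p = 0.131) for LTBP1. Of 34 integrin and focal adhesion genes 0 passed, and 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.803); PTK2, the focal adhesion kinase, had a change of 0.39 (adjusted p = 0.0577, and 0.041 with trended, robust eBayes) and LIMS1 of 0.44 (adjusted p = 0.0653). Of 23 immunoglobulin-like adhesion genes 0 passed, and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.974). CEACAM6 had a change of 0.43 (adjusted p = 0.114) and ICAM2 of -0.35 (adjusted p = 0.151).

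Among 25 Wnt targets, CD44, a hyaluronan receptor, rose by 0.62 (SE 0.07, adjusted p = 0.0332) and LGR5 fell by 1.77 (SE 0.23), while 23 did not pass. Adjusted over the list alone 4 were higher and 3 lower (camera adjusted p = 0.803). LGR5 missed the threshold with cyclic loess (adjusted p = 0.0503) and median centring (adjusted p = 0.0551). SMAD9, a mediator of BMP signalling, rose by 0.61 (SE 0.08, adjusted p = 0.0463) among 24 TGF-β and BMP genes, with 0.06 after cyclic loess and 0.0643 after median centring as its adjusted p; 4 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.803). ID3, outside the naming rule and chosen after its values were seen, did not pass over all clusters but did with the replicate block and with single-symbol clusters only (change 0.84, SE 0.16, adjusted p = 0.123, and 0.039 with the block). EREG, a ligand of the EGF receptor, fell by 0.59 (SE 0.08, adjusted p = 0.0477; 0.0591 after cyclic loess and 0.0541 after median centring) as the only called member of 25 MAPK feedback genes, with 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.343). None of 22 YAP and TAZ targets passed, with 1 higher adjusted over the list alone (camera adjusted p = 0.803), and GADD45A had a change of 0.51 (adjusted p = 0.0832). None of 21 SRF targets, 20 Notch genes, 15 Hedgehog genes and 18 immediate early genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.522, 0.522, 0.995 and 0.974). TAGLN2 had a change of -0.31, DLL4 of -0.15, CDON of 0.23 and MCL1 of 0.23.

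CXCL5 fell by 1.88 (SE 0.16, adjusted p = 0.0112) as the only called gene of 29 NF-κB and inflammatory genes, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.847). None of 29 interferon genes passed either way (camera adjusted p = 0.974), with a change of -0.30 for IFIH1 and 0.25 for GBP1. BIK, a pro-apoptotic BH3 protein, fell by 0.86 (SE 0.06, adjusted p = 0.00329) and 26 other apoptosis genes did not pass; 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.733). ABCB1, a drug efflux pump, fell by 0.77 (SE 0.10, adjusted p = 0.0409) among 22 genes of xenobiotic metabolism and transport, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.803). In that list the CYP1B1 clusters differed in outcome: the cluster with the higher level had a change of 0.41 (adjusted p = 0.132), and another, chosen after its values were seen, of 0.58 (adjusted p = 0.0379, and 0.077 with the replicate block).

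In the test over all clusters, KRT20 was also the only called gene of 28 colonocyte genes, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.803). None of 27 secretory lineage genes passed, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.847); the goblet cell factor SPDEF had a change of 0.53 (adjusted p = 0.111, and 0.046 without Δα-Cat replicate 1). None of 24 mucin and glycan genes passed, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.974), and MUC1 had a change of 0.21 (adjusted p = 0.195). In the test over all clusters, markers of cells the culture should lack gave no call: 0 of 13 fibroblast, 0 of 15 leukocyte and 0 of 14 endothelial markers passed (camera adjusted p = 0.947, 0.974 and 0.847), and adjusted over the list alone only 1 leukocyte marker was lower. CD14 had a change of -0.64 (adjusted p = 0.12), CD68 of 0.66 (adjusted p = 0.506), LUM of 0.11 and PLVAP of -0.11. Of 11 housekeeping genes 0 passed and 2 were lower adjusted over the list alone (camera adjusted p = 0.733); TFRC, the transferrin receptor, had a change of -0.45 (adjusted p = 0.0894) and HPRT1 of -0.36 (adjusted p = 0.187). With an estimated correlation no list was called, and fry called 0 lists as moving one way.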

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

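All alternatives reported here were chosen before the data were examined. Of the 31 called genes that the naming rule takes, 31 kept their direction in every alternative run on them. For most settings the direction was fixed in advance. The groups of these genes did not overlap, so leaving out or weighting an array could not reverse a sign. The replicate block, the eBayes options and the unmoderated test return the same change. All 31 stayed called with trended, robust eBayes and with array weights. The replicate block kept 26, cyclic loess 26, median centring 25 and the unmoderated unequal-variance test 0. Leaving out an array kept between 13 and 23. Clusters called, 224, became 458 among clusters above the median level and 662 with single-symbol clusters only (each a part of the clusters). They became 1 with the unmoderated test and 29 to 120 without 1 array (fewer samples). The unmoderated test gave 4448 clusters at an unadjusted p under 0.05, and limma 6439. Clusters higher in Δα-Cat, 138, became 91 with median centring, 274 above the median level, 369 with single-symbol clusters, 0 unmoderated and 19 to 85 without 1 array. Clusters changed at least 2-fold, 51, became 33 with single-symbol clusters, 0 unmoderated, 11 with treat and 25 to 55 without 1 array. Genes, 140, became 302 above the median level, 658 with single-symbol clusters, 655 with the mean of a gene's clusters (both also adjusted over fewer tests, so averaging itself was not isolated), 0 unmoderated and 21 to 80 without 1 array; 20 genes were called in all 6 of those fits and 67 in none. Other alternatives moved the counts less. Genes became 94 with median centring, 95 with the replicate block, 111 with cyclic loess and 114 with repeated quantile normalization, but 151 with array weights and 173 with trended, robust eBayes. Clusters became 150, 156, 184, 187, 244 and 271 in the same order. Lists called, 4, became 3 with trended, robust eBayes, 0 with an estimated correlation and 0 with fry, and 4 to 5 without 1 array. CTNNA1 had a change of -1.235 with an adjusted p of 0.389 in the unmoderated test, against 0.000256 to 0.0237 in its other alternatives. The replicate block gave 156 clusters, 112 of them shared, and changed no call of a list or named gene beyond those given in the text. No list that was called changed direction; some uncalled values near 0, such as those of CDH3 and CTNNA3, changed sign. Called genes outside the naming rule were not run under every alternative. The causes were not tested. Filters changed both how many clusters were tested and which ones. Clusters without exactly 1 symbol gave 82 calls of 42840, against 224 of 65526 in all. Signal over background could not be assessed.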

Other observations

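The tests in this part were chosen after the result was seen, except the comparison of cluster calls between splits, the check for a mislabelled array and the scan for long segments. Histone genes of the replication-dependent and H1 classes, which formed no fixed list, lay lower in Δα-Cat in 26 of 29 measured members, with a median change of -0.36; the class was chosen after its members were seen to be lower. H1-3 (below the olfactory receptor reference of 4.43 in both groups), H2BC9 and H2BC26 fell, by 0.93, 0.65 and 0.46 on the log2 scale (limma adjusted p = 0.044, 0.0483 and 0.0474). They were called in 0 of the 6 fits without 1 array, and H2BC26 had an adjusted p of 0.0812 with the replicate block. The mean of the class was 6.30 ± 0.09 in Δα-Cat and 6.61 ± 0.12 in α-Cat (SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays allow). All 6 measured CYP4F genes, which encode fatty acid hydroxylases, had a positive change, and 3 were called higher: CYP4F11 (0.63), CYP4F12 (0.61) and CYP4F3 (0.52), with adjusted p of 0.0796, 0.0569 and 0.0784 with the replicate block. Without 1 array, CYP4F11 and CYP4F12 were called in 1 of 6 fits and CYP4F3 in 0. These copies are alike in sequence, so their probes may share signal. Without pairs of a common symbol stem, 2 neighbouring pairs of called genes were left against 1.03 by chance (permutation p = 0.2749).

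Small changes shared by a gene class also appeared in 502 zinc finger genes named ZNF, of which 347 had a positive change (median 0.04), 7 were called higher and 0 lower. With the replicate block ZNF426, ZNF266, ZNF416 and ZNF585A lost the call (adjusted p = 0.0698, 0.084, 0.0974 and 0.0905). Without 1 array ZNF462 was called in 1 of 6 fits and the other 6 genes in 0. Among windows of 31 consecutive expressed genes, the largest median, 0.128, lay among zinc finger genes of chromosome 19, above the 0.108 that marked the 95th percentile of the largest median in 1000 shuffles. Of 24 tubulin genes 18 had a negative change (median -0.17) and 0 were called; the difference of the class mean was -0.16, and another split of the arrays, which kept those numbered 1 together, gave 0.16; the splits that part every pair gave at most 0.077. In all, 10 classes were looked at after the data were seen. The difference of the class mean was 0.11 for C/D box and 0.13 for H/ACA box small nucleolar RNAs, sizes reached by 5 and 7 of 10 splits, and by 1 and 2 of the 4 that part every pair. It was 0.12 for S100 genes (median 0.04, S100A4 called of 22), 0.14 for aminoacyl-tRNA synthetases (median 0.08, IARS1 called of 17) and 0.17 for guanylate-binding proteins (median 0.02, GBP2 and GBP3 called of 7), against at most 0.052, 0.106 and 0.078 in the other splits. It was 0.04 for heat shock proteins (median 0.01, HSPH1 called of 23), against 0.041 in another split. These means include the called genes, which favours the real split. For S100 genes, synthetases and guanylate-binding proteins the medians lay at percentiles 97.27, 96.32 and 71.03 of 10000 level-matched lists. A shift of the whole class was therefore not shown for these classes. IARS1, GBP2 and GBP3 lost the call with the replicate block (adjusted p = 0.0502, 0.0995 and 0.0949) and were called in 1, 0 and 0 of the 6 fits without 1 array. GBP2 (3.27 in Δα-Cat and 2.82 in α-Cat) lay below the olfactory receptor reference of 4.43 in both groups. So did the mean of the guanylate-binding class (3.53 and 3.36). An unnamed transcript cluster, TC01003050.hg.1, rose from 4.90 ± 0.03 to 8.79 ± 0.84 (SD, n = 3 each; log2 change 3.89, limma adjusted p = 0.0162).

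The calls as a whole were compared with the 9 other splits of the 6 arrays. The real split gave 224 clusters, 51 clusters at 2-fold and 140 genes, each matched by 1 of 10 splits, itself, and the highest of the others was 0; 10 splits are too few for a share under 0.05. Replicate numbers may pair the arrays. The 3 other splits that part every same-numbered pair gave 0 clusters, as did the 6 that keep a pair together. For lists, 5 of 10 splits called at least 4, the highest other calling 5, so the list calls did not set the real split apart. A mislabelled array is argued against, since 0 arrays correlated better with the other group than with their own. The margin was narrow for Δα-Cat replicate 1, with a mean correlation of -0.169 with its own group and -0.228 with the other. Each subpopulation is described as a subclone, so a difference between clones unrelated to α-catenin may account for any of these calls and was not tested.

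For the lower cell cycle list, no biological explanation was tested. A single array is argued against as the cause: the list median stayed negative without each array, at most -0.216. A shift of all genes of that level is argued against too, as the median was at percentile 0.0 of 10000 level-matched lists. The grouping stays open: the list mean was 7.54 ± 0.13 in Δα-Cat and 7.84 ± 0.14 in α-Cat (SD, n = 3 each; exact permutation test, two-sided, p = 0.2), and 2 of 10 splits gave a difference as large, the real one of -0.299 and another of 0.308, which kept the arrays numbered 1 together. The 3 other splits that part every pair gave at most 0.165.

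A stretch of the X chromosome held 5 called genes among 12 consecutive measured ones: HMGN5 (1.08, with both group means below 4.43), SH3BGRL (1.64) and RPS6KA6 (1.83) rose, and further along POF1B (-1.29) and KLHL4 (-1.59) fell. Chance placement is argued against by 10000 draws of called genes matched on level (permutation p = 0.0004, adjusted over 5 window lengths, and 0.0149 without HMGN5, which was called in 1 of the 6 fits without 1 array while the other 4 were called in all 6), although over the whole genome only 3 adjacent pairs were both called, against 1.09 by chance (permutation p = 0.0958). A copy number change of 1 continuous segment across all 5 called genes is argued against by the 2 that fell beside 3 that rose. A segment limited to the genes that rose, or to those that fell, was not tested and stays possible. So does a pair of adjoining segments that changed in opposite directions. Across the genome, a shift of at least 0.4 over 31 or more expressed genes, the bound set beforehand, is argued against by the largest absolute window median of 0.128. No biological explanation was tested.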
